A study of Mus musculus with 12 samples.

How the data were processed

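Messenger RNA was measured in 12 libraries of C17.2 cells, a mouse neural progenitor line, with 1 library for each of 2 stable lines, 2 treatments and 3 times. Per the labels' protocols, cells spent 24 h in medium without serum before T3 at 1e-07 M was added or not, were harvested after a further 6, 12 or 24 h, and polyA RNA was reverse-transcribed. Per the series title, the libraries were digital gene expression libraries, in which short sequence tags stand for transcripts. The submitters' processing notes name the genome build mm9. The aligner, the rule that assigned tags to genes and the filters were not given in the sources used here.

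The authors deposited 1 table with 12774 gene symbols and 12 columns of RPM, tags scaled to a common library total, a unit read from the values: each column had the sum of such a unit within rounding. Low values mostly lay on steps, and the step is what 1 tag is worth. Between 86.3% and 93.8% of the low values of a library were whole multiples of its step, with a tolerance of 0.0055 RPM, and the rest were fractions, so whole tags were not recovered and no test on counts was run. The step gives an implied depth of 7.13e+06 to 1.91e+07 tags per library, and 3 tags then correspond to 0.157 to 0.421 RPM. This floor covers counting error only. A symbol had an N/A in 1 library or more in 1877 cases, with a median of 0.42 RPM for the highest value of such a symbol, and N/A was read as 0. Of these symbols 28 had a highest value over 5 RPM, and 13 of the 28 had the N/A in the C17.2a T3 24 h library, so a 0 there need not mean a low level. The highest value, 73.69 for S100a9, belongs to a symbol with its N/A in the C17.2b untreated 12 h library. The other C17.2b libraries had 0.1 to 0.32 RPM of it. Of the symbols, 11837 were current, 836 matched a current symbol through a unique synonym and 101 matched none, in a RefSeq list of genes. Transcripts of the GENCODE M21 annotation of GRCm38 served for GC content only. No coordinates are printed because that build is not the authors'.

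The statistics used log2(RPM + 1) and limma 3.58.1 in R 4.3.3, with lmFit, eBayes with a trend, and Benjamini-Hochberg adjustment over the genes tested at a threshold of 0.05. A fold change on this scale understates the change of genes with low RPM. Genes with at least 1 RPM in at least 3 libraries of a fit were tested, which left 10577 genes for T3 and 10192 for untreated cells. This filter was set once the unit was known and before any test. The tests, the gene lists, the rule for named genes and the first set of alternatives were chosen before the data were examined. That plan had a count-based test for a table of counts and limma for normalized values, and limma was used because the table holds RPM.

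No group had a second library. The 6 pairs of a T3 and an untreated library from the same line and time served as repeats, with each pair as a block, so the spread contains real differences of the response between times and lines. No label says that libraries came from separate cultures, and the p-values measure the spread between these pairs, not between replicate cultures. The tests covered the response shared by all 6 pairs (5 residual degrees of freedom), the response in each line and their difference (4), the response at each time and its difference between times (3), the lines without T3 with time as a block (2), and 24 h against 6 h without T3 with line as a block (2). Single pairs were described without a p-value by the genes with at least 50 implied tags in the pair and a ratio of at least 2-fold, after a prior of 2 tags per library was added.

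Of 34 gene lists, 32 had at least 5 measured members and were tested with camera from limma at a preset correlation between genes of 0.01, on log2(RPM + 1), adjusted over the lists of each comparison. The estimated correlation and fry were the alternatives. Named genes were, for the shared response, each line and the untreated lines, the 12 highest and the 12 lowest log2 fold changes among genes past 0.05 with 1 sign in every pair and a mean of at least 20 implied tags. For the differences between lines and between times they were the 5 smallest p, none having passed. The 5 smallest p were taken at each time and the 6 highest and 6 lowest for time without T3. The receptors Thra and Thrb and the targets Klf9 and Hr were always named, while Dio3 and Thrsp were not analysed here. Some genes that this rule picks are not reported here. For each list described, up to 4 members with the smallest p were named. The 12 values of 84 tested genes equalled those of another symbol at 1 decimal. None of the genes chosen by size or by smallest p over all genes was among them.

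The alternatives were median-ratio scaling, no filter, a filter at 5 RPM, voom on implied tags, pseudocounts of 0.5 and 5, no time block, each line alone, all 12 libraries for the untreated lines, time in hours as a number, other tag limits and priors for single pairs, and leaving out each pair or time in turn. Quantile normalization, robust eBayes, a loess correction of each library for GC content (span 0.5) and leaving out the 24 h libraries were added after seeing the data. GC content, the median over a gene's whole transcripts, was known for 10484 genes, 99.1% of those tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.

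The scripts were tested on simulated libraries with the real genes' means and spreads, in 5 draws that together changed 500 genes at each of 2-fold and 4-fold (496 at 4-fold between the untreated lines). Of the 2-fold and 4-fold changes, 73.8% and 97.4% were recovered for the shared response, where 10505 to 10521 genes were tested, 47% and 89.6% in C17.2a (10512 to 10526 genes), and 41.2% and 87% in C17.2b (10508 to 10536 genes). For the difference of the lines 11.2% and 67% were recovered (10509 to 10526 genes), and for the difference between times 0.8% and 30.4% (10518 to 10524 genes). At single times 17.2% to 18.8% of the 2-fold and 73.2% to 77.2% of the 4-fold changes were recovered, with 10510 to 10534 genes tested. For untreated cells the shares were 33.2% and 90.3% between the lines (10193 to 10217 genes) and 14.6% and 72.6% between 24 h and 6 h (10259 to 10277 genes). False calls made up 5% to 10.8% of the calls. A first draw alone had given a higher false share for the difference of the lines, and the number of draws was then raised to 5. In a simulated table with 25 changed genes planted as a list, camera's adjusted p for that list was 1.83e-49 at the preset and 0.00218 with the estimated correlation. Of the 32 other lists 0 passed either way. The noise of each gene was drawn independently of other genes, so this does not check the preset correlation. Each gene also had the same spread in every library and every test, that of the shared T3 fit. The shares above therefore need not hold where a pair has a wider spread, or for tests with another spread, such as those of untreated cells.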

Results

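Gene expression was measured in C17.2 cells, a neural progenitor line from mouse, that had been given a tagged receptor for thyroid hormone. The C17.2a line carried the alpha receptor and the C17.2b line the beta receptor. Each line was left untreated or given T3 (triiodothyronine, the active thyroid hormone) at 1e-07 M for 6, 12 or 24 h, to find the genes that respond to the hormone over time in each line. There were 12 libraries of sequence tags, 1 for each line, treatment and time, so no value below has a replicate within its group. Levels are in RPM, the tags of a gene scaled to a common library total, as deposited. The implied depth ran from 7.13e+06 tags in the C17.2b T3 24 h library to 1.91e+07 in the C17.2b untreated 6 h library. Log2 fold changes refer to log2(RPM + 1), and the error given is the standard error (SE) of the limma fit.

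The libraries separated first by time and not by line or hormone. The first principal component held 52.8% of the variance, and the 4 libraries of 24 h lay at 35.7 to 72.6 on it against -33.8 to -24.3 for the 8 earlier ones. The second component held 16.6%, and the C17.2a T3 24 h library stood alone on it at 66.5, with the other 11 libraries at -23.8 to 13.1. Across genes the Spearman correlation of the C17.2a T3 and untreated libraries of 24 h was 0.91, against 0.966 for the same pair in C17.2b, 0.979 at 6 h in C17.2a and 0.976 at 6 h in C17.2b.

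**Figure D1:**
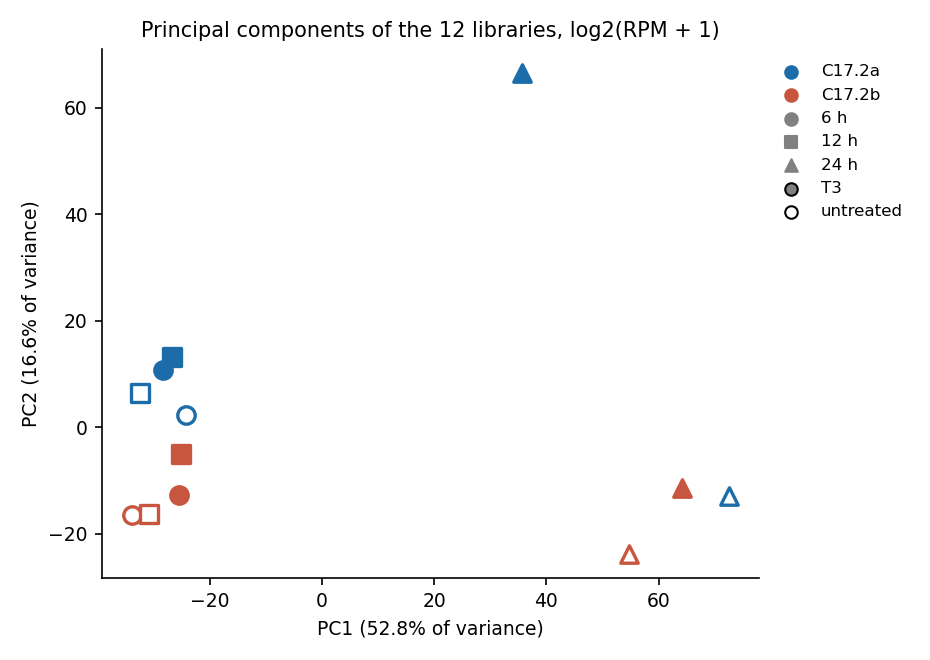
Each point is 1 of the 12 libraries on the first and second principal component of log2(RPM + 1), with the share of variance on each axis; colour gives the line, shape the time and filling the treatment. The 24 h libraries lie at 35.7 or above on the first component, and the C17.2a T3 24 h library lies at 66.5 on the second.

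The receptors themselves were measured at low levels. Thra, the gene of the alpha receptor, lay between 2.04 and 5.83 RPM in 11 libraries and at 0.12 RPM in the C17.2a T3 24 h library. Thrb, the gene of the beta receptor, lay between 0.72 and 2.19 RPM in all 12 libraries. Without T3, the level in C17.2b minus that in C17.2a was 0.08 (SE 0.19) for Thra and -0.02 (SE 0.20) for Thrb on the log2 scale, with adjusted p of 0.852 and 0.967 in limma. With T3, the shared log2 fold change was -0.52 (SE 0.31) for Thra and 0.30 (SE 0.15) for Thrb, with adjusted p of 0.451 and 0.335 in limma. The Thra log2 ratio was -2.42 in the C17.2a 24 h pair and -0.36 to 0.17 in the other 5, and the shared value without that pair was -0.13. A transgene may lack the natural 3' end of its gene, and the rule that assigned tags to genes was not given. Whether these levels include the transgene is therefore unknown, and they do not check which receptor a line carries.

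On the log2(RPM + 1) scale, T3 raised Epas1, a transcription factor of the hypoxia response, more than any other gene named for the shared response. That scale understates changes from low levels, so the rank need not hold for ratios of RPM. The shared log2 fold change of Epas1 was 4.14 (SE 0.13, n = 6 pairs), or 17.7-fold on that scale. Its untreated levels of 1.89 to 8.47 RPM became 48.41 to 193.44 RPM. Hr, a corepressor that binds thyroid hormone receptors, rose by 3.55 (SE 0.12) and the potassium channel Kcna1 by 3.52 (SE 0.15). Klf9, a transcription factor and known T3 target, rose by 1.16 (SE 0.26), although its log2 ratio was -0.40 in the C17.2a 24 h pair and 1.18 to 1.75 in the other 5. The call of Klf9 was lost without any single one of those 5 pairs (adjusted p 0.101 to 0.127 in limma), without a filter (0.0535) and without a time block (0.109). The strongest fall on that scale among the genes named was that of Kctd12, an auxiliary subunit of GABA receptors, at -2.23 (SE 0.11).

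Flrt1, a membrane protein with leucine-rich repeats, rose by 3.77 (SE 0.37), the chemokine receptor Cxcr7 (now Ackr3) by 3.27 (SE 0.27), and the cytokine signalling suppressor Socs2 by 3.17 (SE 0.17). The amino acid transporter Slc43a2 rose by 2.92 (SE 0.14), the phosphatase Phospho1 by 2.80 (SE 0.22) and the matrix protein Npnt by 2.71 (SE 0.19). Lpin3, a phosphatidate phosphatase, rose by 2.70 (SE 0.33), the arrestin relative Arrdc3 by 2.69 (SE 0.22) and the glial glutamate transporter Slc1a2 by 2.68 (SE 0.23). Slc1a2 was listed at 0.18 RPM or less, or as N/A, in all 6 untreated libraries and at 3.09 to 13.02 RPM with T3.

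The phospholipid transporter Atp10b changed by -2.07 (SE 0.16), the G protein regulator Rgs16 by -1.98 (SE 0.33), the adhesion proteins Cdsn and Chl1 by -1.91 (SE 0.25 and 0.16), and Mcam by -1.66 (SE 0.18). Epb4.1l4b (now Epb41l4b), of the band 4.1 family, changed by -1.71 (SE 0.14), the myelin lipid-binding protein Pmp2 by -1.69 (SE 0.29) and the synaptic adhesion protein Lrrtm2 by -1.68 (SE 0.17). The polarity gene Prickle2 changed by -1.62 (SE 0.19), the potassium channel subunit Kcnmb4 by -1.58 (SE 0.17) and the vesicle protein Syt4 by -1.57 (SE 0.13). These 24 genes had 1 sign in all 6 pairs by the rule that chose them. Their adjusted p in limma lay between 1.34e-06 (Epas1) and 0.0099 (Pmp2), with 0.0322 for Klf9. Without a time block Cdsn (0.0611), Mcam (0.0672) and Epb4.1l4b (0.102) lost their call.

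In all, 682 of 10577 genes passed 0.05 after Benjamini-Hochberg adjustment in limma, 433 higher and 249 lower with T3, and 649 of them had 1 sign in all 6 pairs. Of all genes tested 14.3% did, against 3.1% if signs were even and independent between pairs. No label states that the pairs are independent, and genes are not independent replicates, so 3.1% is no baseline for chance. Without the C17.2a 24 h pair the same test called 1554 genes, 950 higher and 604 lower, among them 679 of the 682, and without a time block it called 240. Leaving out the C17.2b 12 h, C17.2a 12 h, C17.2b 6 h or C17.2b 24 h pair gave 319, 379, 404 or 419 genes.

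**Figure D2:**
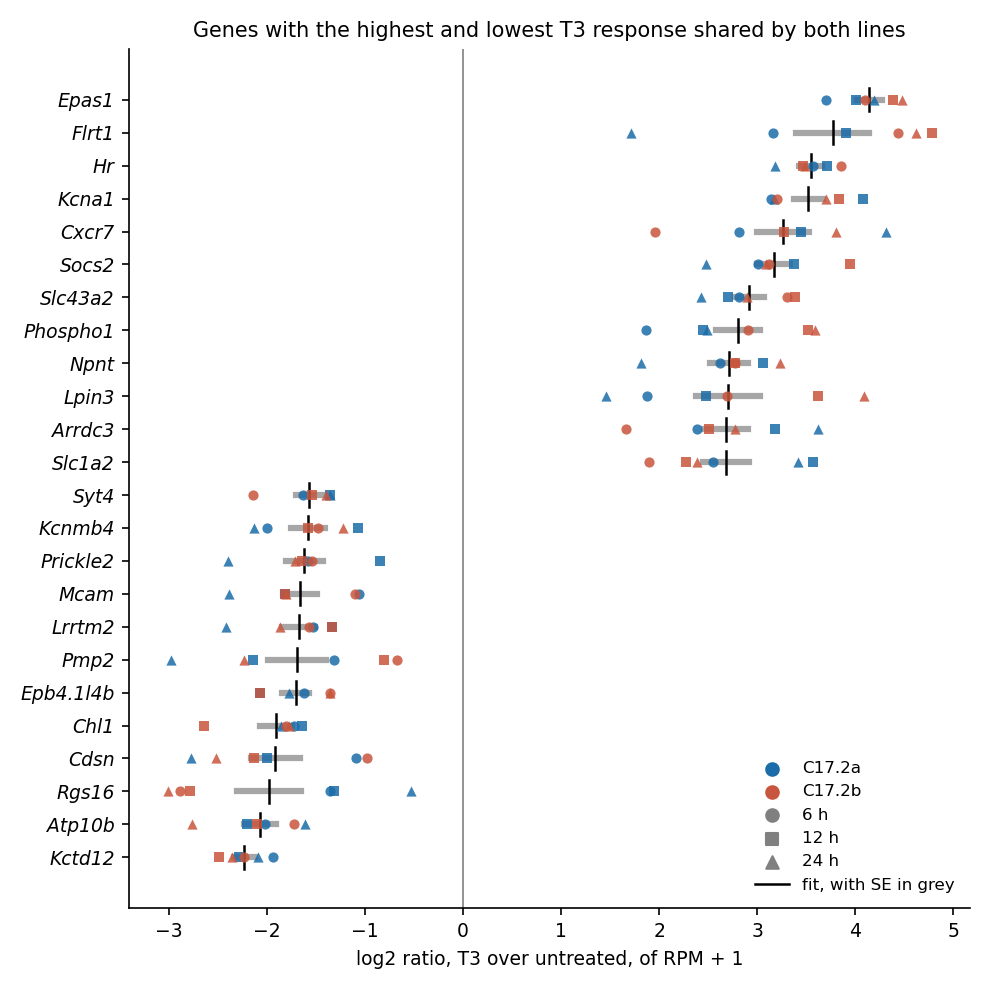
The log2 ratio of T3 over untreated (RPM + 1) is shown in each of the 6 pairs, with the fitted value as a black bar and its SE in grey. The genes are the 12 highest and 12 lowest of the shared test among those named, which required 1 sign in every pair. Epas1 lies between 3.70 and 4.48 in the 6 pairs and Kctd12 between -2.49 and -1.93, while Flrt1 and Rgs16 lie closer to 0 in the C17.2a 24 h pair than in the other 5.

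Genes of the hypoxia response rose together. Of 26 measured members 16 rose and 0 fell, or 24 and 0 when adjusted over the list alone, and the median log2 fold change of the list was 0.85. Besides Epas1, the prolyl hydroxylase Egln1 rose by 0.90 (SE 0.12), the mitophagy gene Bnip3 by 1.42 (SE 0.19) and the oxidoreductase Ero1l (now Ero1a) by 1.53 (SE 0.21). The adjusted p of the list in camera (limma) was 8.95e-20 at the preset correlation, while the adjusted p was 0.265 with an estimated correlation. Glycolysis and glucose uptake genes, of which Hk2, Ldha, Pdk1, Pgk1 and Slc2a1 also belong to the hypoxia list, had 5 of 22 members higher and 1 lower, or 14 and 1 adjusted over the list alone. The regulator of glycolysis Pfkfb3 rose by 1.24 (SE 0.13), the glucose transporter Slc2a1 by 0.93 (SE 0.14) and hexokinase Hk2 by 0.57 (SE 0.11), and the lactate dehydrogenase subunit Ldhb changed by -0.72 (SE 0.13). This list's adjusted p was 8.36e-08 in camera (limma) and the adjusted p was 0.289 with an estimated correlation.

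Of 25 measured genes listed beforehand as T3-responsive, 10 rose and 2 fell, or 16 and 2 adjusted over the list alone. Besides Hr, the lipogenic factor Srebf1 rose by 1.07 (SE 0.11) and the signal transducer Stat5a by 1.37 (SE 0.16), and the neurofilament gene Nefm changed by -1.56 (SE 0.13). The adjusted p of this list was 4.89e-07 in camera (limma) and the adjusted p was 0.265 with an estimated correlation. Fatty acid synthesis genes had 5 of 22 members higher and 0 lower, or 9 and 2 adjusted over the list alone, with the desaturase Scd1 at 1.31 (SE 0.10), the acyltransferase Dgat2 at 1.27 (SE 0.19) and malic enzyme Me1 at 1.19 (SE 0.24). Its adjusted p was 0.0231 in camera (limma) and the adjusted p was 0.348 with an estimated correlation. Circadian clock genes had 4 of 16 members higher and 1 lower, with the same counts adjusted over the list alone, and included Hlf at 1.40 (SE 0.18), Bhlhe40 at 1.63 (SE 0.24), Nr1d2 at 0.54 (SE 0.11) and Nfil3 at -1.12 (SE 0.17). Their adjusted p was 0.0231 in camera (limma) and the adjusted p was 0.494 with an estimated correlation. Bhlhe40 also belongs to the hypoxia list. The T3-responsive list shares Srebf1, Me1, Fasn and Acaca with fatty acid synthesis, Dbp with the clock and Slc2a1 and Hif3a with hypoxia. These lists are therefore not separate findings.

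Of 5 lists that passed with a test that pointed down, that of cytoskeletal genes and targets of the serum response factor had the smallest p. Of its 24 members 0 rose and 3 fell, or 0 and 7 adjusted over the list alone, among them vinculin (Vcl, -0.51, SE 0.08), tropomyosin (Tpm1, -0.73, SE 0.14) and filamin (Flna, -0.51, SE 0.12). The adjusted p was 6.41e-06 in camera (limma), and the adjusted p was 0.265 with an estimated correlation. Neural progenitor markers had 1 of 16 members higher and 5 lower, or 1 and 7 adjusted over the list alone. Notch1 changed by -0.87 (SE 0.10), vimentin (Vim) by -1.04 (SE 0.16) and Sox2 by -1.12 (SE 0.18), while the hedgehog pathway factor Gli3 rose by 0.82 (SE 0.14). This list's adjusted p was 0.0231 in camera (limma) and the adjusted p was 0.348 with an estimated correlation, and the call was lost without the C17.2b 6 h pair (adjusted p 0.0639 in camera).

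Wnt targets had 1 of 16 members higher and 1 lower, or 2 and 4 adjusted over the list alone, with cyclin D (Ccnd1) at -1.39 (SE 0.14) and the receptor Fzd7 at 0.83 (SE 0.20). Their adjusted p was 0.0233 in camera (limma), the adjusted p was 0.265 with an estimated correlation, and it was 0.0515 in camera without the C17.2a 12 h pair. Extracellular matrix genes had 0 of 29 members higher and 5 lower, or 1 and 6 adjusted over the list alone, including Has2 at -1.44 (SE 0.18), tenascin (Tnc) at -1.39 (SE 0.19), Adam12 at -1.23 (SE 0.23) and nidogen (Nid1) at -0.67 (SE 0.15). Cytosolic ribosomal protein genes had 0 of 67 members past the threshold, all genes and list alone, with a median of -0.11. The adjusted p in camera (limma) was 0.0277 for matrix genes and 0.00124 for ribosomal genes, and the adjusted p was 0.577 and 0.557 with an estimated correlation. Both lists had their lowest median log2 ratio in the C17.2a 24 h pair, -0.84 for matrix and -0.49 for ribosomal genes, against -0.10 to 0.14 and -0.20 to 0.05 in the other 5 pairs, and both calls were lost without that pair (adjusted p 0.205 and 0.0636 in camera). They were also lost without the 24 h libraries (0.106 and 0.526), and that of matrix genes with a GC correction (0.0529).

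**Figure D3:**
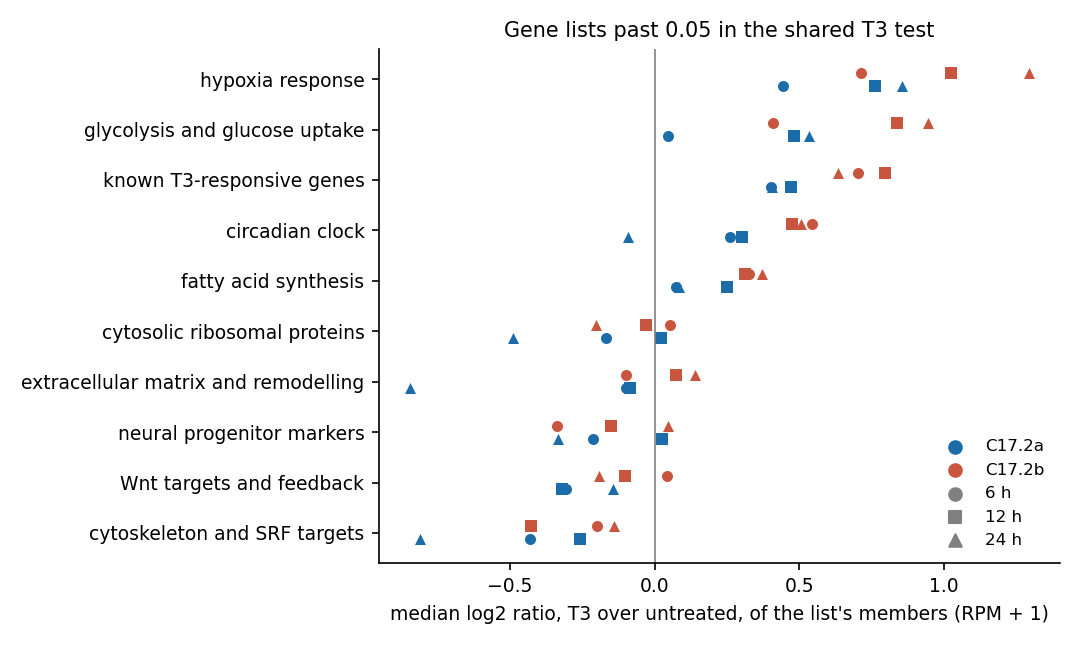
Points show, for each pair, the median log2 ratio of T3 over untreated (RPM + 1) over the measured members of the 10 gene lists past 0.05 in the shared camera test; colour gives the line and shape the time. The hypoxia list lies between 0.44 and 1.29, above 0 in all 6 pairs, and the matrix list at -0.84 in the C17.2a 24 h pair.

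In C17.2a, the line with the alpha receptor, Epas1 rose by 3.97 (SE 0.17, n = 3 pairs), Cxcr7 by 3.52 (SE 0.37), Hr by 3.49 (SE 0.18) and Kcna1 by 3.46 (SE 0.21). Slc1a2 rose by 3.18 (SE 0.25), Arrdc3 by 3.06 (SE 0.28), Socs2 by 2.95 (SE 0.23), Flrt1 by 2.93 (SE 0.36) and Slc43a2 by 2.65 (SE 0.17). Npnt and Phospho1 rose 5.64- and 4.80-fold (log2 SE 0.26 and 0.20). The lowest values were those of Pmp2 (-2.15, SE 0.37), Kctd12 (-2.10, SE 0.14), Cdsn (-1.95, SE 0.37), Atp10b (-1.95, SE 0.23), Epb4.1l4b (-1.82, SE 0.20) and Mcam (-1.75, SE 0.26). Chl1, Kcnmb4, Nefm and Gas7, a growth arrest gene, changed by -1.74, -1.73, -1.66 and -1.64 (SE 0.22, 0.24, 0.18 and 0.16), and Prickle2 and Epb4.1l3 (now Epb41l3) by -1.61 and -1.56 (SE 0.28 and 0.23). Adjusted p in limma ran from 8.08e-05 (Epas1) to 0.0493 (Cdsn), and Klf9 at 0.75 (SE 0.33) did not pass in this line (adjusted p 0.311), while without the C17.2a 24 h pair it rose by 1.32 (adjusted p 0.00171 in limma). From this line's libraries alone 12 genes passed, 11 higher and 1 lower: of the 12 lower genes named here Kctd12 passed (adjusted p 0.0489 in limma), and the other 11 lost their call (0.0703 for Gas7 to 0.263 for Prickle2), as did Flrt1 (0.133) and Npnt (0.0989). Of the same 12, 8 lost it without the 6 h pair of this line, 8 without that of 12 h and 0 without that of 24 h. Without a time block 9 lost it, and without the C17.2b 6, 12 or 24 h pair 3, 6 or 4. Of the 12 higher genes that the rule picks, 3 lost it without the 6 h pair of C17.2a (adjusted p 0.0599 to 0.0865 in limma). Without that of 12 h 2 did (0.0545 to 0.127).

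In C17.2a 145 genes passed 0.05 in limma, 96 higher and 49 lower. The count was 462 without the C17.2a 24 h pair, 32 without that of 6 h, 35 without that of 12 h, 73, 49 and 70 without the 6, 12 or 24 h pair of C17.2b, 28 without a time block and 12 from this line's libraries alone. Of the gene lists 6 passed in camera, again with the hypoxia list first: 3 of 26 members rose and 0 fell, or 18 and 0 adjusted over the list alone (P4ha2 at 0.97, SE 0.18, adjusted p 0.0412 in limma), with an adjusted p of 8.14e-15 in camera and an adjusted p of 0.482 with an estimated correlation. The matrix list had 0 members higher and 1 lower, or 0 and 3 adjusted over the list alone, with an adjusted p of 0.00486 in camera, 0.146 without the 24 h pair, and an adjusted p of 0.619 with an estimated correlation.

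In C17.2b, the line with the beta receptor, Flrt1 rose by 4.61 (SE 0.36, n = 3 pairs), the water channel Aqp1 by 4.47 (SE 0.73), Epas1 by 4.32 (SE 0.17), Hr by 3.60 (SE 0.18) and Kcna1 by 3.58 (SE 0.21). Aqp1 went from 3.39 to 6.10 RPM untreated to 62.94 to 195.28 RPM in this line, and in C17.2a its log2 ratio was 4.36 at 6 h, 3.71 at 12 h and -0.16 at 24 h. Lpin3 rose by 3.47 (SE 0.30), Socs2 by 3.38 (SE 0.23), Phospho1 by 3.34 (SE 0.20), Slc43a2 by 3.19 (SE 0.17), Cxcr7 by 3.01 (SE 0.37), Npnt by 2.93 (SE 0.26) and Tmem117 by 2.91 (SE 0.21). Rgs16 changed by -2.89 (SE 0.18), Kctd12 by -2.36 (SE 0.14), Atp10b by -2.19 (SE 0.23), Chl1 by -2.08 (SE 0.22), and the matrix gene Adamtsl1 by -2.03 (SE 0.20). Cdsn, the kinase anchor Akap12, the surface protein Ly6a, and Arid5a changed by -1.87, -1.80, -1.79 and -1.77 (SE 0.37, 0.23, 0.28 and 0.28), and Tmem200c and Syt4 by -1.71 and -1.69 (SE 0.23 and 0.19). Adjusted p in limma ran from 4.06e-05 (Epas1) to 0.0351 (Cdsn), and Klf9 rose by 1.56 (SE 0.33, adjusted p 0.047 in limma), a call lost without any single pair of this line (adjusted p 0.196 to 0.344) or the C17.2a 6 h pair (0.0796), without a filter (0.0777), without a time block (0.222) and with GC correction (0.0561). Aqp1, Cdsn, Arid5a and Tmem200c also lost theirs without any single pair of this line, Akap12, Ly6a and Cxcr7 without that of 12 or 24 h, and Syt4 without that of 12 h (0.0515). Without a time block Atp10b, Lpin3, Cdsn, Arid5a, Tmem200c, Akap12 and Ly6a lost theirs (0.0618 for Lpin3 to 0.543 for Cdsn).

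In C17.2b 329 genes passed 0.05 in limma, 238 higher and 91 lower. The count was 1178 without the C17.2a 24 h pair, which enters through the shared estimate of the spread, 1086 from this line's libraries alone, 119, 39 and 56 without its own 6, 12 or 24 h pair, and 86 without a time block. Of the gene lists 13 passed in camera. The hypoxia list had 12 of 26 members higher and 0 lower, or 21 and 0 adjusted over the list alone, among them the growth factor Vegfa, 5.66-fold higher (log2 SE 0.30), and the lysyl hydroxylase Plod2 at 1.52 (SE 0.19), with an adjusted p of 6.37e-20 in camera (limma) and an adjusted p of 0.271 with an estimated correlation. The glycolysis list had 6 of 22 members higher and 0 lower, or 17 and 1 adjusted over the list alone, with an adjusted p of 2.15e-10 in camera and an adjusted p of 0.271 with an estimated correlation. Of immediate early genes 0 of 26 rose and 1 fell, the same adjusted over the list alone: Jun, at -1.46 (SE 0.12). Its adjusted p was 0.000885 in limma, while the list's was 0.0175 in camera, 0.216 without the C17.2b 6 h pair, and the adjusted p was 0.384 with an estimated correlation. At the preset correlation the list passed in 9 of 12 settings.

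The lines were compared to find genes whose response depends on the line, which differ in the receptor and in all else that separates these stable lines. Tgm2, a transglutaminase, had the smallest p: its log2 ratios were 2.31 to 2.97 in the 3 pairs of C17.2b and 0.67 to 0.79 in those of C17.2a, a difference of 1.96 (SE 0.22, n = 6 pairs), with an adjusted p of 0.178 in limma. Rgs16 was next, with a difference of -1.83 (SE 0.25) and an adjusted p of 0.433, followed by the phosphatase inhibitor Ppp1r14c at 1.94 (SE 0.40), the glycosylation gene Ost4 at 0.94 (SE 0.20) and the receptor Mrgprf at 1.31 (SE 0.28), each with an adjusted p of 0.722 in limma. For Hr the difference was 0.12 (SE 0.25), which turned negative in 5 alternatives, for Klf9 0.82 (SE 0.47), for Thra 0.65 (SE 0.62) and for Thrb -0.12 (SE 0.31). In limma 0 genes passed 0.05, with 583 at an unadjusted p under 0.05, and 0 passed in voom. Without the C17.2a 24 h pair Tgm2 (1.97) and Rgs16 (-1.56) passed, both with an adjusted p of 0.00807 in limma. Scaling moves the median of this difference over all genes from 0.125 to -0.005 (median-ratio), and values are to be read against it.

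The calls of the lines overlapped. Of the 96 and 238 genes higher in C17.2a and C17.2b, 82 were the same, against 2.2 for independent lists. Of the 49 and 91 lower genes 30 were the same, against 0.42. Both sets of calls came from the same fit, with a shared spread for each gene. Genes of small spread can thus pass more easily in both lines, and 2.2 and 0.42 are no baseline for chance. In C17.2b all 96 and 49 genes called in C17.2a had the same sign, and in C17.2a 237 of 238 and 89 of 91 called in C17.2b did. Across 10577 genes, which are not independent replicates, the responses of the lines correlated at r = 0.513 (Spearman's rho 0.297), and the highest of the 15 other swaps of T3 and untreated within pairs gave 0.395. The value was 0.71 without the C17.2a 24 h pair. The S phase and the mitosis lists passed in camera for the difference of the lines, with adjusted p of 0.00173 and 0.000998. For both the adjusted p was 0.862 with an estimated correlation, and without the 24 h libraries it was 0.377 and 0.544 in camera. In the fry test of limma, which does not compare a list with other genes, it was 0.524 and 0.624.

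**Figure D4:**
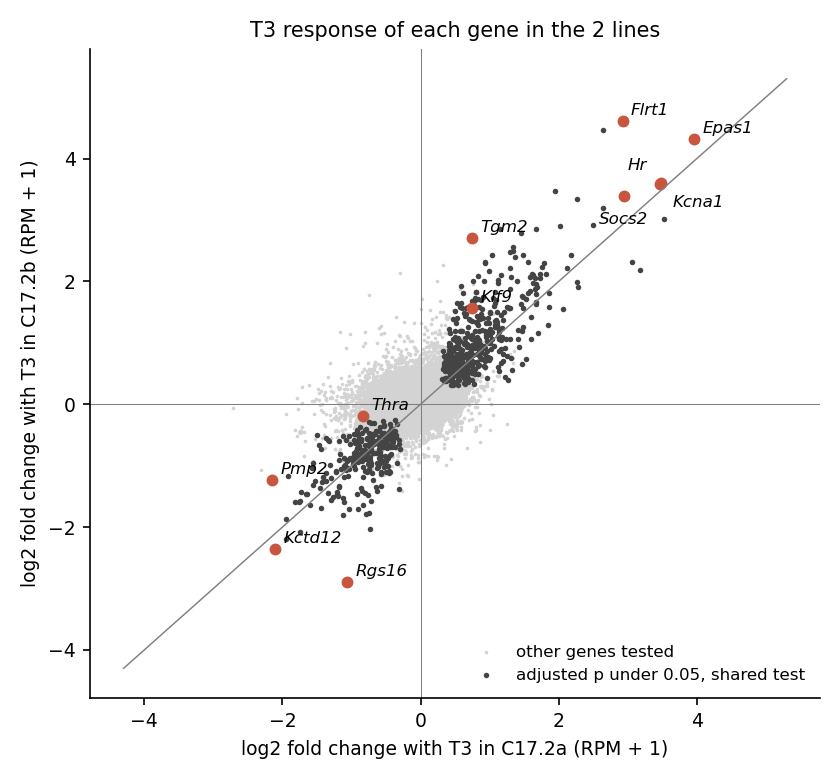
Each point is 1 of 10577 genes, with its fitted log2 fold change with T3 (RPM + 1) in C17.2a on the horizontal and in C17.2b on the vertical axis; dark points passed 0.05 in the shared test, red points are named genes and the slanted line marks equal values. Epas1 (3.97 and 4.32) and Hr (3.49 and 3.60) lie near the line, and Rgs16 (-1.07 and -2.89) and Tgm2 (0.74 and 2.70) lie off it.

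At 6 h after T3, Epas1 (3.90, SE 0.22), Hr (3.71, SE 0.22), Kcna1 (3.17, SE 0.19), Socs2 (3.06, SE 0.24) and Slc43a2 (3.06, SE 0.26) had the smallest p over both lines (n = 2 pairs), with adjusted p of 0.00232 to 0.0123 in limma. At 12 h they were Kcna1 (3.96, SE 0.19), Epas1 (4.20, SE 0.22), Hr (3.59, SE 0.22), Socs2 (3.66, SE 0.24) and Cxcr7 (3.36, SE 0.26), with adjusted p of 0.00154 to 0.00949 in limma. At 24 h Epas1 (4.34, SE 0.22), Kcna1 (3.44, SE 0.19), Hr (3.34, SE 0.22), Cxcr7 (4.06, SE 0.26) and Ero1l (2.22, SE 0.16) led, with adjusted p of 0.00202 to 0.00374 in limma. The hypoxia list passed at each time, with a median log2 fold change of 0.58, 0.90 and 1.02. Its adjusted p in camera (limma) was 5.04e-11, 4.23e-24 and 2.77e-18, and the adjusted p was 0.524, 0.404 and 0.592 with an estimated correlation. Of its 26 members 1, 4 and 5 rose and 0 fell, or 9, 19 and 19 adjusted over the list alone. In limma 17 genes passed at 6 h (12 higher), 52 at 12 h (38 higher) and 112 at 24 h (72 higher). Without the C17.2a 24 h pair the counts were 680 at 6 h and 690 at 12 h, and without the C17.2b 24 h pair 682 and 690. The spread of these fits comes from the 6 and 12 h pairs alone. Without any other single pair, the counts at times that kept 2 pairs fell to between 0 and 26. No count is given for a time left with 1 pair, which has no spread of its own.

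Between times, Appl2, an adaptor of endosomal signalling, had the smallest p for a changing response, with log2 ratios of -0.26, 1.22 and 2.08 at 6, 12 and 24 h in C17.2a and -0.31, 1.29 and 2.06 in C17.2b, and an adjusted p of 0.338 in limma. The chloride channel gene Clic1 had ratios of -3.51 and -2.47 at 24 h and of -0.53 to 0.73 before, the nucleolar gene Nol6 of 2.25 and 2.29 at 24 h and of -0.05 to 0.55 before. The protease inhibitor Serpine2 went from -0.61 and -0.68 at 6 h to -2.27 and -1.97 at 24 h, and the carbonic anhydrase Car9 from 0.57 and 0.54 to 3.11 and 3.31. The adjusted p of these 4 genes was 0.941 to 0.944 in limma. In limma 0 genes passed 0.05, with 291 at an unadjusted p under 0.05, and 0 passed in voom. Without all 24 h libraries Appl2 alone passed. No count is given without a single pair, because 1 pair would then stand for its time.

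The single pairs were set side by side without a test. Genes with a ratio of 2-fold or more numbered 346, 350 and 2417 at 6, 12 and 24 h in C17.2a and 492, 447 and 620 in C17.2b. In the C17.2a 24 h pair 604 were higher and 1813 lower, while in the other 5 pairs more were higher than lower. The SD of the log2 ratio over genes was 1.09 in that pair and 0.46 to 0.57 in the others.

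Without T3 the lines differed most on the log2(RPM + 1) scale, among the genes named, in Rtn4rl1, a receptor of the Nogo family. It was lower in C17.2b by a log2 fold change of -4.90 (SE 0.18, n = 3 times). Its level was 33.40 to 51.03 RPM in C17.2a and 0.21 to 0.54 RPM in C17.2b. The calcium-binding protein S100a9 (-4.49, SE 0.36), the secreted signalling protein Wisp2 (now Ccn5; -3.32, SE 0.20), phospholipase Plb1 (-3.15, SE 0.23), the microfibril protein Mfap5 (-2.90, SE 0.36) and the Wnt antagonist Sfrp1 (-2.58, SE 0.19) were also lower in C17.2b. Pdgfrl, Ogn, Vsnl1, Car9 and Igfbp6 were at -2.48, -2.42, -2.40, -2.29 and -2.21 (SE 0.17, 0.16, 0.21, 0.24 and 0.25). Higher in C17.2b were Adamtsl1 (2.79, SE 0.18), the microtubule kinase Mark1 (2.68, SE 0.19), the collagen Col15a1 (2.51, SE 0.20), the growth factor Btc (2.45, SE 0.14) and the receptor phosphatase Ptprz1 (2.41, SE 0.22). B3galt2, Negr1, Ndn, Cyfip2, Pcdh20, Prex1 and the brain lipid-binding protein Fabp7 followed at 2.29, 2.10, 2.07, 2.05, 2.05, 2.03 and 2.02 (SE 0.20, 0.23, 0.23, 0.17, 0.12, 0.14 and 0.20). Adjusted p in limma ran from 1.45e-06 (Rtn4rl1) to 0.00116 (Mfap5).

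Of 10192 genes 902 passed 0.05 in limma between the untreated lines, 299 higher and 603 lower in C17.2b, so 33.1% of the calls were higher, against 43.4% after median-ratio scaling and 43.7% after quantile normalization. The count was 404 without the 6 h libraries, 439 with all 12 libraries in the fit, and 1 (Rtn4rl1) without a time block. In the fit over all times, all 30 measured genes of G2 and mitosis lay higher in C17.2b, 8 past the threshold and 25 adjusted over the list alone, with cyclin B (Ccnb1) at 1.35 (SE 0.27), the centromere gene Cenpa at 1.26 (SE 0.25) and cyclin F (Ccnf) at 0.99 (SE 0.18). Their adjusted p was 1.13e-14 in camera (limma) and the adjusted p was 0.708 with an estimated correlation. At the preset correlation it was highest, 4.11e-09 in camera, without the 6 h libraries. Whether the difference is the same at each time was not tested.

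Mesenchymal markers had 1 of 21 members higher and 7 lower in C17.2b, or 2 and 11 adjusted over the list alone, with Loxl1 at -1.46 (SE 0.16), the collagen Col1a1 at -1.29 (SE 0.19) and fibronectin (Fn1) at -1.21 (SE 0.24). Wnt targets had 1 of 16 higher and 6 lower, or 1 and 7 adjusted over the list alone, including Bmp4 at -1.32 (SE 0.17). Interferon response genes had 0 of 18 higher and 5 lower, or 1 and 10 adjusted over the list alone, including the class I histocompatibility genes H2-K1 and H2-D1 at -1.20 and -0.96 (SE 0.14 both). Cytoskeletal genes had 0 of 23 higher and 5 lower, or 0 and 9 adjusted over the list alone, including Cyr61 at -1.15 (SE 0.12). The adjusted p of these 4 lists in camera (limma) was 0.00234, 0.00574, 0.00234 and 0.000175, and for each the adjusted p was 0.708 with an estimated correlation.

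Over time without T3, the mitotic kinase Plk1 rose by 4.06 (SE 0.34, n = 2 lines) from 6 to 24 h, from 2.16 and 10.16 RPM to 97.48 and 98.20 RPM. Rai1 rose by 3.30 (SE 0.23), the myosin chaperone Unc45a by 3.29 (SE 0.25), the mitotic kinesin Kif4 by 3.28 (SE 0.32), Pih1d1 by 3.22 (SE 0.26) and Islr by 3.21 (SE 0.38). The translation factor Eif4g1 changed by -2.78 (SE 0.20), the dynein light chain Dnalc1 (now Dnal1) by -2.77 (SE 0.18), S100a11 by -2.75 (SE 0.16), Mcee by -2.67 (SE 0.27), Mrps6 by -2.55 (SE 0.42) and Siglecg by -2.54 (SE 0.50). Adjusted p in limma lay between 1.61e-05 and 0.00192 for these 12 genes. With robust eBayes 2 of the 6 lower ones lost their call (adjusted p 0.067 and 0.095 in limma). In limma 5720 of 10192 genes passed 0.05, 4384 higher and 1336 lower at 24 h. Scaling moved the median over all genes from 0.40 to -0.02, and with it the share of calls that were higher from 76.6% to 48.2% (median-ratio) or 49.2% (quantile). The labels name no batch, and time cannot be told apart from any batch that the 24 h libraries shared.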

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

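The tests of depth, of untreated cells, of a differing response, of GC content as a whole cause, the swaps and the other splits of the libraries were chosen only after the results were seen. For the difference of the lines, genes of S phase and DNA replication lay lower than the other genes tested, with an adjusted p of 0.00173 in camera (limma), and so did genes of G2 and mitosis, with 0.000998. The adjusted p was 0.862 for both with an estimated correlation. The fry test of limma, which asks whether a list itself differs between the lines, gave adjusted p of 0.524 and 0.624, so only the rank against other genes passed. The response in C17.2b minus that in C17.2a had a median of -0.16 over 32 S phase genes, of which 8 lay above 0, and of -0.14 over 31 mitosis genes, of which 9 did. Of single genes 0 passed in limma, with Cdt1, which licenses replication origins, at -0.96 and the mitotic kinase Cdk1 at -0.87, both with an adjusted p of 0.722 in limma. In the single pairs the median of the S phase list was -0.04, -0.06 and 0.31 at 6, 12 and 24 h in C17.2a and 0.03, -0.16 and -0.20 in C17.2b, and that of the mitosis list -0.13, -0.08 and 0.07 against -0.09, -0.07 and -0.49. Without the 24 h libraries the adjusted p in camera was 0.377 and 0.544. It was 0.0644 for S phase without the C17.2a 24 h pair and 0.222 for mitosis without the C17.2b 24 h pair.

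The C17.2a 24 h pair stood apart: its log2 ratios correlated at 0.056 to 0.219 with those of the other 5 pairs, which correlated at 0.457 to 0.641 with each other. Lower depth is argued against by an SD of the ratio 1.7 times that of the C17.2b 24 h pair (0.821 and 0.483) at genes of at least 50 RPM, where counting error is small, and a library from untreated cells by 154 of 202 genes raised at least 2-fold in the other pairs that lay above 0 in this one, 76.2% against 44.1% of all genes. An earlier form of that test, on 950 raised genes, gave a median of 0.239 and decided nothing. A loss of tags that depends on the GC content of whole transcripts had the values it needs as a part of the difference, with rho = -0.383 between GC content and the departure of this pair. As the whole, such a loss is argued against: 2554 genes lay 2-fold or more from the other pairs before a GC correction and 2370 after it, with 1829 in both. A loss that depends on the GC content of the tags themselves was not tested. A response of C17.2a that differs at 24 h from 6 and 12 h stays open, with 2436 genes 2-fold or more from the earlier pairs against 350 in C17.2b, since the group holds 1 library.

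The 4 libraries of 24 h stood apart from the 8 earlier ones, with SDs of the log2 change of 0.955 and 0.788 from 12 to 24 h in C17.2a and C17.2b against 0.381 and 0.287 from 6 to 12 h. A trend with the GC content of whole transcripts as the whole of this is argued against by 5747 genes past 0.05 after GC correction, with 5720 before it. As a part it stays open, with rho of 0.216 in C17.2b and 0.271 in C17.2a between GC content and the change. A gradual change in medium without serum also stays open: the change from 6 to 12 h in 1 line correlated at 0.074 and -0.132 with that from 12 to 24 h in the other, while the change from 12 to 24 h correlated at 0.831 between the lines. A batch shared by these libraries cannot be told apart from time, because each time has its own libraries and no label names a batch.

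For the shared response, 1 of the 32 swaps of T3 and untreated within pairs, the real one, gave as many genes as 682. The highest other gave 21. A share of 1 in 32 is the smallest that these swaps can give, and it lies under 0.05. This argues against a chance assignment of T3 within pairs, if the pairs are independent, which no label states. In C17.2a (145 genes, highest other 0), C17.2b (329, highest other 0) and the untreated lines (902, highest other 0), 1 of 4 swaps, the real one, gave as many, and the swaps are too few for a share under 0.05. For the difference of the lines 10 of 10 splits, and for the difference between times 6 of 6, gave as many as the real 0, with a highest other of 0. Any split reaches a count of 0, so these decide nothing, and they too are too few for a share under 0.05.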

How the results depend on the processing

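Quantile normalization, robust eBayes, the GC correction and leaving out the 24 h libraries were chosen after seeing the data. Counts of genes past 0.05 in limma are given where they moved by over 1.5 times. Without the 24 h libraries 1370 genes passed for the shared response, 680 in C17.2a, 1012 in C17.2b, 6 for the difference of the lines (Tgm2, Rgs16, Osr1, Hspa1b, Dmpk and Enho, named after their values were seen), 1 (Appl2) between times, and 675 each at 6 and 12 h. Without a time block there were 240, 28 and 86 for the shared response, C17.2a and C17.2b, and 1 (Rtn4rl1) between the untreated lines, a setting that puts the time differences into the error. C17.2a libraries alone gave 12 and C17.2b libraries alone 1086, and all 12 libraries 439 between the untreated lines. At 6 h median-ratio scaling gave 26, no filter 11 and quantile normalization 29, at 12 h no filter and a pseudocount of 5 gave 30 each, and at 24 h quantile normalization gave 169. With pairs left out in turn (leave-one-out) the ranges were 319 to 1554 shared, 32 to 462 in C17.2a, 39 to 1178 in C17.2b, 0 to 2 between the lines, 0 to 2840 between times, 0 to 682 at 6 h, 0 to 690 at 12 h and 0 to 4305 at 24 h, and with times left out 404 to 1047 between the untreated lines. With a pair left out, 1 pair stands for its time and is assumed to vary like the others. Where a time kept 2 or 3 genes, these were Epas1, Kcna1, Hr or Cxcr7. In single pairs a minimum of 20 tags gave 521 genes at 6 h in C17.2a, and the highest minimum tried gave 186, 202 and 1554 at 6, 12 and 24 h in C17.2a and 287, 272 and 370 in C17.2b, since fewer genes are then counted. The correlation of the lines was 0.688 without the 24 h libraries and 0.356 to 0.71 with pairs left out. Gene lists passing fell to 0 in all 8 comparisons with an estimated correlation. With fry 8 passed in C17.2b, 2 between the untreated lines and 0 for the difference of the lines and at 6, 12 and 24 h. For the difference of the lines 6 passed with quantile normalization, and at 12 h 13 without the 24 h libraries. With pairs left out the range of lists was 2 to 5 for the difference of the lines, 3 to 11 at 6 h, 6 to 13 at 12 h and 6 to 11 at 24 h. Signs turned, none past 0.05 in limma, for Thrb in C17.2b (-0.005 without the C17.2b 12 h pair, and up to 0.423 with others left out) and in the difference of the lines for Hr (-0.013 with median-ratio scaling, -0.068 with voom, -0.196 with GC correction, -0.034 without the C17.2a 24 h pair, -0.008 without the C17.2b 6 h pair), Thra (-0.147 without the C17.2a 24 h pair, -0.104 without the 24 h libraries) and Thrb (0.067 without the C17.2b 6 h pair). With other pairs left out these reached 0.231 for Hr, 1.15 for Thra and -0.361 for Thrb. Except where the setting itself is named above as the reason, the cause was not tested. Of 141 values of named genes, the number with the same direction and side of 0.05 was 140 with voom and with median-ratio scaling, 141 with quantile normalization and a pseudocount of 0.5, 138 with a pseudocount of 5 and with robust eBayes, 139 with GC correction and 134 with no filter. It was 68 of 114 with no time block, 13 of 27 with C17.2a libraries alone, 27 of 27 with C17.2b libraries alone, 100 of 105 without the C17.2a 24 h pair, and 78 to 90 of 104 or 105 without another single pair, where 14 to 25 calls were lost. Tests on counts were not run because whole tags were not recovered, library totals alone and the table as deposited equal the values used, a filter at 5 RPM stood in for one on counts, and median-ratio scaling for size factors. At 3 tags a library cannot resolve levels under 0.157 to 0.421 RPM.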

Other observations

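The test that follows Epas1 was chosen only after the result was seen. Besides Nefm, given above, the neurofilament gene Nefl fell by -0.82 (SE 0.18), with an adjusted p of 0.0257 in limma. Both belong to a list of neuron markers with 0 of 10 members higher and 2 lower, or 1 and 3 adjusted over the list alone, whose adjusted p was 0.125 in camera. The adjusted p was 0.506 with an estimated correlation. Of 26 immediate early genes 1 was higher and 3 were lower, or 2 and 5 adjusted over the list alone, and the list did not pass, with an adjusted p of 0.0977 in camera. The adjusted p was 0.557 with an estimated correlation. Jun changed by -1.34 (SE 0.09), Atf3 by -0.88 (SE 0.18) and Fosl2 by -0.48 (SE 0.12), while Fosl1 rose by 0.83 (SE 0.20), with adjusted p of 1e-04, 0.019, 0.0488 and 0.0402 in limma. The inducible chaperone Hspa1b rose by 2.12 (SE 0.28), Osgin1, a gene of the oxidative stress response, by 1.69 (SE 0.19), and Ddit4, an inhibitor of the mTOR kinase, by 1.05 (SE 0.16), with adjusted p of 0.00295, 0.00113 and 0.0051 in limma. The lists of chaperones and of the oxidative stress response did not pass, with adjusted p of 0.237 and 0.251 in camera. The adjusted p was 0.557 and 0.577 with an estimated correlation. The glial pump subunit Atp1b2 rose by 1.63 (SE 0.29), with an adjusted p of 0.0117 in limma.

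Of 387 symbols with an N/A in 1 library only, 115 had it in the C17.2a T3 24 h library.

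As a hypothesis, the rise of the hypoxia list could follow that of Epas1, a transcription factor with a high response. In C17.2b 24 of 26 members had a larger ratio at 24 h than at 6 h, against 243 of 417 other genes that rose in the shared test, and in C17.2a 19 of 26 against 222 of 417. Epas1 is itself 1 of the 26; without it the numbers were 23 of 25 and 18 of 25. The medians of the list had shown this rise before, and a slow rise of any other origin gives the same, so the hypothesis stays open. The 417 genes had also passed a test whose spread includes differences between times, which disfavours growing responses. The 26 members had not been filtered so, and the comparison thus leans toward the list. A direct effect of T3 on each gene was not tested. A trend with the GC content of whole transcripts and scaling by library totals are argued against by medians of 0.855 after GC correction and 0.838 after median-ratio scaling, beside 0.847.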
